A study of Mus musculus with 28 samples.

How the data were processed

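Total RNA of 28 mouse cell cultures was hybridized to single-channel expression arrays after biotin labelling, per the labels' protocols. The authors deposited a single matrix of 35556 probe sets by 28 arrays whose values are log2 signal, from 3.757941 to 14.46866. MAS5 is the only tool that the submitters' processing notes name. How signals were summarized and scaled, and the tool's version, are not given in the sources used here. All 28 columns were used (0 columns not used). No count or read depth exists for such data, and the number of arrays (3 to 6 per group) limits the precision. The half-width of the 95% interval of a log2 difference had a median over genes of 0.15 for GMT against 0F, 0.11 for NGMT against GMT, 0.15 for HNGMT against HGMT and 0.20 for DMNT against DMT. That for DMNT against DMT rests on 1 DMT array, replicate 4, which is taken to vary like the other groups.

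Groups were taken from the sample titles, although the source-name label describes 0F like all other samples as selected cells: 0F (3 arrays), GMT (5), NGMT (6), HGMT (3), HNGMT (3), DMT (4) and DMNT (4). A distance between the sorted values of arrays placed the arrays in 3 sets of nearly equal distribution (largest mean distance inside a set 0.0486 log2, smallest between sets 0.135). Set 1 held 8 arrays, set 2 held 15 and set 3 held 5. The sets are not named in the labels, and set 1 is the series of samples named MEF and a number.

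The annotation table pairs 21789 probe sets with 1 gene symbol, 1621 with several and 12146 with none. Only those with 1 symbol were named. No symbol changed when matched through its Entrez ID to a RefSeq gene table of assembly GRCm38.p6, which was used for names alone. Each of 19938 genes was read from its probe set of highest mean, and 12211 genes whose signal lay above the array median of all probe sets on at least 3 arrays were tested.

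Differences were tested with limma 3.58.1 in R 4.3.3, by lmFit, contrasts and eBayes with trend, in 1 fit over all 28 arrays with group and set as terms (19 residual degrees of freedom). Tests were two-sided, p was adjusted by Benjamini-Hochberg over genes in each comparison, and genes were called at an adjusted p under 0.05. There were 13 comparisons of groups and 2 interaction contrasts. The plan made before the data were examined assumed unlogged signal with an added constant of 16 and a series term of 2 levels taken from the sample names. The deposited values were already on the log2 scale and fell into 3 separately scaled sets, so the fit used them as deposited with a 3-level set term. Both planned choices were run as alternatives, and the closing section gives their counts.

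Set 1 holds all 0F arrays, so HGMT, HNGMT, DMT and DMNT are compared with 0F through the GMT and NGMT arrays of sets 1 and 2, and DMNT also through DMT replicate 4. That array carries no weight in comparisons of DMT with GMT or 0F. That assumes an additive difference between sets. A direct difference after quantile normalization, without a set term, was therefore added after the data were seen.

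Gene lists were fixed before the data were examined, from textbook knowledge: sarcomere, calcium handling, ion channels and gap junctions, delivered factors, other cardiac transcription factors, atrial and natriuretic, ventricular, fibroblast and extracellular matrix, smooth muscle, skeletal muscle, cell cycle, oxidative metabolism, p53 and DNA damage response, interferon response, TGF-beta response, macrophage, endothelial, epithelial (with mesothelial genes), neural and glial, adipocyte, and cartilage and bone. Of 525 list entries, 500 had a named probe set and 383 were tested. Genes may stand in more than 1 list, as Des, Myl7 and Gja5 do. Lists were tested with limma's camera (preset correlation of 0.01, adjusted over lists in each comparison), and again with an estimated correlation, and with limma's fry.

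The rule for named genes was also fixed beforehand. It took the 6 delivered factors, the 8 largest rises and 8 largest falls among called genes whose groups did not overlap inside each set that holds both (the plan spoke of series), and up to 4 called members of each list with the largest change. Where fewer than 2 members of a list were called it took up to 2 of smallest p, and for interactions up to 6 called genes. It selected 1091 gene and comparison pairs, of which the text names part, chosen after their values were seen and from pairs that kept their direction under the alternatives run. Nppa in HGMT against 0F was added outside the rule. Of 156 such values between groups, 75 had 1 group below the array median on all its arrays of a set that holds both groups (of any set where none does).

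The fit was tested on simulated data with 100 genes changed by 0.5 and 100 by 1 on the log2 scale in each of 13 comparisons of 12211 genes. At a change of 0.5 it recovered 94% for GMT against 0F, 95% for NGMT against GMT, 74% for DMNT against DMT and 45% for DMNT against 0F, and at a change of 1 it recovered 94% for DMNT against 0F. The simulation gave every array the same error, the 1 DMT array of set 3 included. A shifted list, sarcomere, was called in 13 of 13 comparisons, and over them camera also called 13 of the lists that had not been shifted. Some of those share genes with the sarcomere list, as Myl4, Myl7 and Ttn. Simulated errors were drawn independently for each gene, so the check does not cover correlation between members of a list.

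Alternatives covered the added constant (1, 64 and 16), quantile normalization, no filter and a stricter filter, the mean over probe sets, no set term, the 2-level series term, arrays of 1 series or 1 set, the replicate number as a block, the compared groups alone, array weights, and leaving out each array. Genes called in all 6 combinations were counted beside 20 simulated data sets in which the groups did not differ. Up to 100 other splits of the samples were fitted for each comparison, and up to 100 that keep each group's number of arrays in each set.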

Results

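Gene expression was measured on 28 single-channel mouse arrays from embryonic fibroblasts (MEFs) that received combinations of cardiac transcription factors or no factor. In the names of the combinations, G stands for GATA4, M for MEF2C, T for TBX5, N for NKX2.5, H for Hand2 and D for MYOCD. There were 3 arrays of MEFs without factors (0F), 5 of GMT, 6 of NGMT, 3 of HGMT, 3 of HNGMT, 4 of DMT and 4 of DMNT. Cells with factors also received the doxycycline-controlled activator rtTA and a reporter that ties zeocin resistance to a troponin T promoter. They were cultured with 2 μg/mL doxycycline, selected with 300 μg/mL zeocin for 7 days and collected on day 21. By their titles and protocol the 0F cells were MEFs without virus, also collected on day 21. The source-name label, which is the same for all 28 samples, names selected cells for 0F too, and the titles were followed here. On that reading each comparison with 0F spans transduction, medium, doxycycline and selection together with the factors. Differences are log2 fold changes ± standard error from a limma fit over all arrays, with each gene read from 1 probe set. A gene is said to rise or fall where its adjusted p passed the threshold. The mark † stands where a compared group lay below the array median of all probe sets on all its arrays of a set. The files give no detection call, so that signal may be background, and the size of a marked value is not exact. The number of arrays limits the precision.

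Array medians of log2 signal lay in 3 separate ranges, which mark 3 sets of arrays scaled apart from each other. They ran from 6.68 to 6.75 in set 1 (all 0F arrays, GMT replicates 1 and 2, NGMT replicates 1 to 3), from 6.86 to 6.95 in set 2 (the other GMT and NGMT arrays, all HGMT and HNGMT arrays, DMT replicates 1 to 3) and from 7.64 to 7.65 in set 3 (DMT replicate 4 and all DMNT arrays). Sets 1 and 2 differed in more than scale: after quantile normalization of their 11 GMT and NGMT arrays, 8814 of 12211 genes differed between the sets, 483 of them by at least 2-fold. Car3, an adipocyte-rich carbonic anhydrase, was higher in set 2 than in set 1 within the same combinations (4.24 ± 0.16†), as was the interferon-induced Oas2 (1.59 ± 0.10). The mesothelial antigen Msln (-3.05 ± 0.08), the atrial peptide gene Nppa (-1.71 ± 0.11) and the calcium-binding Casq2 (-1.81 ± 0.07†) were lower. All 9 members of the epithelial list were lower in set 2 (adjusted p = 0.599 with an estimated correlation) and 24 of 31 interferon-response members were higher (adjusted p = 0.924 with an estimated correlation). The set was a term of every fit. GMT and NGMT share set 1 with 0F, and their arrays of set 2 enter through the set term. HGMT, HNGMT, DMT and DMNT reach 0F only through the GMT and NGMT arrays of both sets, and DMNT also through DMT replicate 4. That array, alone of its group in set 3, adds nothing to DMT in other comparisons, which rest on DMT replicates 1 to 3. For these 4 combinations the direct difference, taken after quantile normalization of all arrays and without a set term, stands beside each gene value, and list counts carry the number of members called higher by both. That alternative was chosen after the data were seen.

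Among the delivered factors, the probe sets of Hand2 and Myocd gave higher signal where the factor was added. Hand2 signal was higher in HGMT than in GMT (2.71 ± 0.07, 3 and 5 arrays) and in HNGMT than in NGMT (2.69 ± 0.07, 3 and 6 arrays). Myocd, the gene of the smooth and cardiac muscle coactivator myocardin, was higher in DMT than in GMT (3.63 ± 0.07†, 3 and 5 arrays). Against 0F, Hand2 was called higher in 5 of 6 combinations (0.20 to 2.96) and Myocd in all 6 (0.30 to 4.14). Both counts include combinations that did not receive the factor. The probe sets of the other delivered factors followed delivery little or not at all. Mef2c was lower than in 0F in all 6 combinations (-0.77 to -0.58), and Tbx5 differences against 0F ran from -0.56 to -0.31 with 5 called lower. Gata4 ran from -0.14 to 0.30 against 0F, with 2 called higher (GMT and HGMT, neither as a direct difference). Among the 7 comparisons of combinations it ran from -0.30 to 0.08, and only DMT against GMT, which removes GATA4, was called (-0.30). There Mef2c ran from -0.10 to 0.19 and Tbx5 from -0.20 to 0.05, with none called. Nkx2-5 ran from -0.09 to -0.02 against 0F, and Nkx2-5 was not called in any of the 7 comparisons among combinations (-0.06 to 0.06). Whether the probe sets of the delivered factors, Hand2 and Myocd included, read the delivered sequences is not given in the sources used here. None of them is therefore used to check delivery.

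The comparison of GMT with 0F asks what this combination, with its culture and selection, changed in fibroblasts. Sarcomere genes rose: 23 of 27 members rose and 1 fell (23 and 1 adjusted over the list alone), among them Tnnt2, the cardiac troponin T gene whose promoter carried the selection (5.10 ± 0.08), the atrial myosin light chains Myl7 (4.82 ± 0.22†) and Myl4 (4.65 ± 0.09), and cardiac alpha-actin Actc1 (3.97 ± 0.20; 5 and 3 arrays throughout). The sarcomere list had camera adjusted p = 2.07e-08, adjusted p = 0.0949 with an estimated correlation. Of the atrial and natriuretic list, 6 of 8 members rose and 0 fell (6 and 0 adjusted over the list alone), with Nppa at 2.88 ± 0.13† (camera adjusted p = 0.00128, adjusted p = 0.0195 with an estimated correlation). Among cardiac transcription regulators the stretch-responsive cofactor gene Ankrd1 rose (6.09 ± 0.13†). In its list 10 of 24 rose and 8 fell (10 and 8 adjusted over the list alone) (camera adjusted p = 0.927). Calcium-handling genes moved in part: 7 of 19 members rose and 3 fell (7 and 3 adjusted over the list alone), including the ryanodine receptor Ryr2 (2.14 ± 0.16†) and junctophilin Jph2 (1.81 ± 0.07) (camera adjusted p = 0.291). Of the ion channel and gap junction genes, 6 of 12 rose and 2 fell (6 and 2 adjusted over the list alone), with connexin 40, Gja5, at 3.24 ± 0.15† (camera adjusted p = 0.359). Among ventricular genes 4 of 7 rose and 1 fell (4 and 1 adjusted over the list alone), with Cdh13 at 3.86 ± 0.11 (camera adjusted p = 0.152). As direct differences after quantile normalization Nppa was 1.84 ± 0.46† and Gja5 1.96 ± 0.52†, smaller by over 1.5 times.

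Genes of other muscle, stress and other cell types moved in the same comparison. Smooth muscle genes rose in number: 15 of 22 members rose and 3 fell (15 and 3 adjusted over the list alone), with desmin, Des (4.66 ± 0.09), and Mustn1 (2.79 ± 0.10) higher and Aoc3 (-4.50 ± 0.11†) and Pgm5 (-3.61 ± 0.09†) lower (camera adjusted p = 0.0142, adjusted p = 0.431 with an estimated correlation). Skeletal muscle genes gave 7 rises and 1 falls among 19 members (7 and 1 adjusted over the list alone) (camera adjusted p = 0.256). Targets of p53 rose: 23 of 27 members rose and 2 fell (23 and 2 adjusted over the list alone), including Perp (3.92 ± 0.06), the p53 ubiquitin ligase Mdm2 (1.55 ± 0.06) and Btg2 (1.62 ± 0.08) (camera adjusted p = 1.17e-07, adjusted p = 0.0195 with an estimated correlation). In the TGF-beta response list 13 of 17 rose and 1 fell (13 and 1 adjusted over the list alone), with Inhba at 1.52 ± 0.10 (camera adjusted p = 0.00970, adjusted p = 0.532 with an estimated correlation). Epithelial and mesothelial genes gave 7 rises and 0 falls among 9 members (7 and 0 adjusted over the list alone), with Msln at 5.14 ± 0.11 (camera adjusted p = 4.60e-05, adjusted p = 0.0978 with an estimated correlation). Cell cycle genes gave 10 rises and 1 falls among 19 members (10 and 1 adjusted over the list alone), including the mitotic kinase Cdk1 (1.14 ± 0.10) (camera adjusted p = 0.247). Among neural and glial genes 3 of 6 rose and 1 fell (3 and 1 adjusted over the list alone), with the intermediate filament gene Nes at 2.36 ± 0.13† (camera adjusted p = 0.497). Of the endothelial genes, 3 of 13 rose and 2 fell (3 and 2 adjusted over the list alone), with Ramp2 at -2.84 ± 0.08† (camera adjusted p = 0.464). Rises outside these lists included Ptgs2, the inducible cyclooxygenase (6.21 ± 0.06†), the acute-phase gene Saa3 (6.19 ± 0.27†), the urothelial gene Upk1b (6.20 ± 0.13†) and the cytokine gene Il6 (5.41 ± 0.26†).

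Fat, macrophage and matrix genes fell in GMT. Each of the adipocyte genes was lower: 0 of 13 members rose and 13 fell (0 and 13 adjusted over the list alone), including Car3 (-7.28 ± 0.25†), resistin, Retn (-6.49 ± 0.31†), and adiponectin, Adipoq (-5.89 ± 0.23†) (camera adjusted p = 2.70e-15, adjusted p = 0.00811 with an estimated correlation). Of the macrophage genes, 2 of 17 rose and 15 fell (2 and 15 adjusted over the list alone), with lysozyme Lyz2 at -6.78 ± 0.56† and the complement gene C1qb at -4.29 ± 0.20† (camera adjusted p = 1.22e-07, adjusted p = 0.201 with an estimated correlation). Oxidative metabolism genes fell: 4 of 36 members rose and 24 fell (5 and 24 adjusted over the list alone), among them the fatty acid transporter Cd36 (-6.53 ± 0.37†), Cox8b (-4.28 ± 0.25†) and the glucose transporter Slc2a4 (-3.02 ± 0.09†) (camera adjusted p = 6.46e-07, adjusted p = 0.107 with an estimated correlation). Cd36, Lpl and Slc2a4 are also expressed by fat cells, whose markers moved with this group. Of the fibroblast and matrix genes 9 of 40 rose and 23 fell (9 and 23 adjusted over the list alone), with elastin, Eln (-3.03 ± 0.15), and periostin, Postn (-2.54 ± 0.19), lower and the metalloproteinase Mmp3 higher (2.32 ± 0.14) (camera adjusted p = 0.00234, adjusted p = 0.585 with an estimated correlation). In the cartilage and bone list 3 of 11 rose and 4 fell (3 and 4 adjusted over the list alone), with Col10a1 at 4.44 ± 0.08† and Comp at -3.16 ± 0.16 (camera adjusted p = 0.437; median -0.10, mean 0.06). Interferon-response genes gave 4 rises and 13 falls among 31 members (4 and 12 adjusted over the list alone) (camera adjusted p = 0.132). Of the delivered factors themselves 3 of 6 rose and 2 fell (3 and 2 adjusted over the list alone) (camera adjusted p = 0.791). Their median was 0.09, their mean -0.03 and camera's direction downward. In all, 7333 of 12211 genes were called, 4386 higher and 2947 lower, 1368 of them by at least 2-fold. The direct difference was smaller by over 1.5 times for Car3 (-4.74 ± 1.06†), Msln (3.28 ± 0.76), Il6 (3.51 ± 0.80†) and Saa3 (4.12 ± 0.89†). Without a set term the median of all genes moved to 0.15.

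NGMT differed from 0F in 7422 genes (4471 higher, 2951 lower; 6 and 3 arrays). Nppa rose by 5.87 ± 0.12†, Tnnt2 by 4.96 ± 0.08, Ankrd1 by 5.99 ± 0.12† and Msln by 5.04 ± 0.11. Among sarcomere genes 23 of 27 rose and 1 fell (23 and 1 adjusted over the list alone), with Myl4 at 4.54 ± 0.09 (camera adjusted p = 5.79e-08, adjusted p = 0.0802 with an estimated correlation). Atrial and natriuretic genes gave 7 rises and 0 falls among 8 members (7 and 0 adjusted over the list alone) (camera adjusted p = 2.73e-04, adjusted p = 0.0123 with an estimated correlation). Of the p53 targets 22 of 27 rose and 2 fell (22 and 2 adjusted over the list alone) (camera adjusted p = 7.48e-08, adjusted p = 0.0137 with an estimated correlation), and of the epithelial genes 8 of 9 rose and 0 fell (8 and 0 adjusted over the list alone) (camera adjusted p = 3.10e-05, adjusted p = 0.0802 with an estimated correlation). Adipocyte genes fell, with 13 of 13 members lower and Adipoq at -5.94 ± 0.22† (camera adjusted p = 2.27e-15, adjusted p = 0.00792 with an estimated correlation). Macrophage genes gave 2 rises and 15 falls among 17 members (2 and 15 adjusted over the list alone), with Lyz2 at -6.22 ± 0.52† (camera adjusted p = 7.48e-08, adjusted p = 0.190 with an estimated correlation). Among oxidative metabolism genes 3 of 36 rose and 27 fell (3 and 27 adjusted over the list alone) (camera adjusted p = 1.12e-07, adjusted p = 0.0802 with an estimated correlation).

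**Figure D1:**
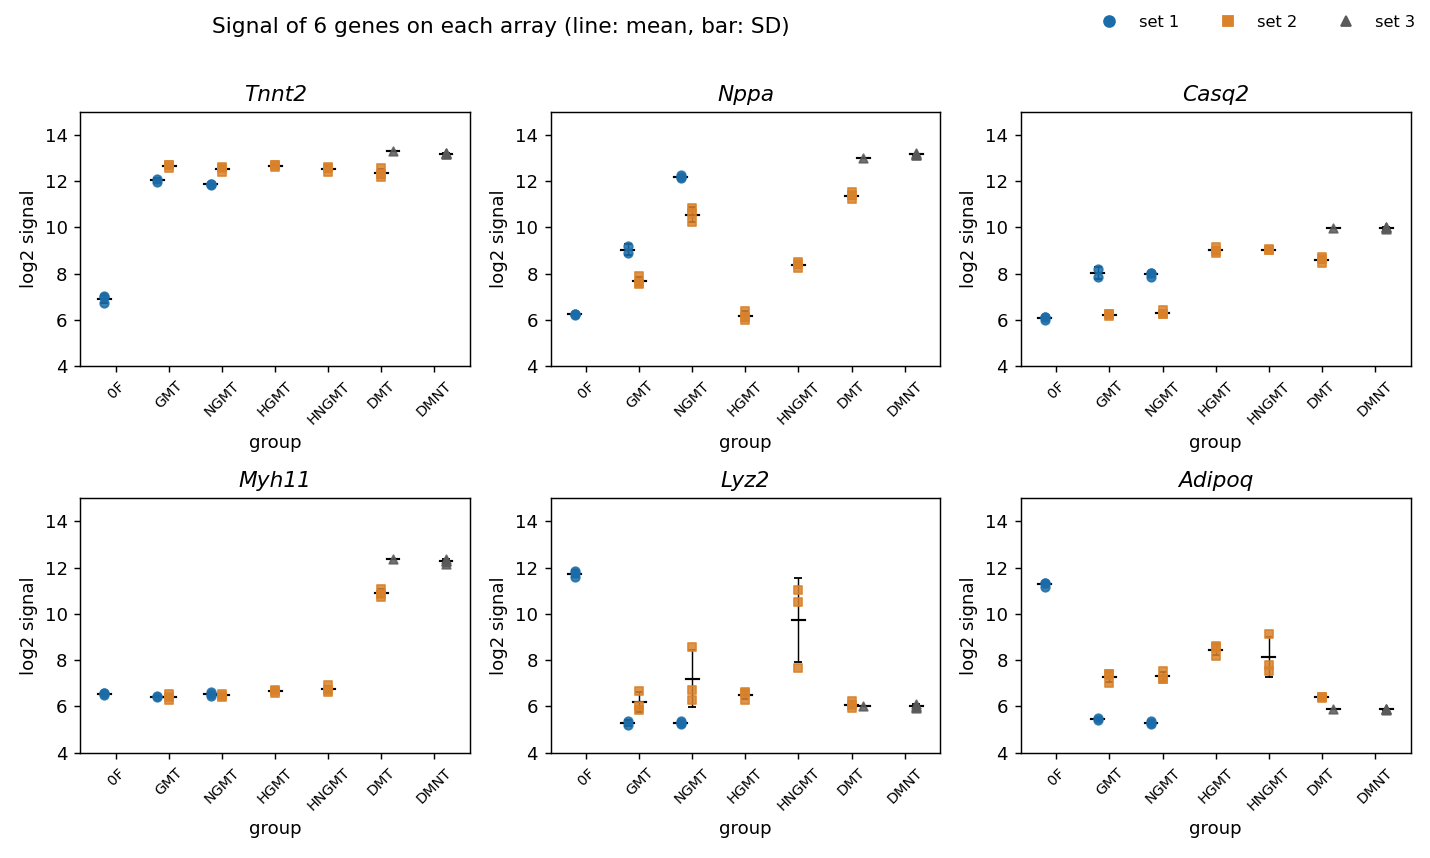
Log2 signal of Tnnt2, Nppa, Casq2, Myh11, Lyz2 and Adipoq on each array, by group (horizontal axis) and by set of separately scaled arrays (colour and marker), with the mean as a line and the SD as a bar where a group has more than 1 array in a set. Nppa averaged 6.25 in 0F, 9.04 in GMT and 12.18 in NGMT within set 1, and 7.67 in GMT, 10.55 in NGMT and 6.16 in HGMT within set 2.

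Adding NKX2.5 to GMT is the comparison of NGMT with GMT, made in both sets. Nppa, which encodes atrial natriuretic peptide, rose by 2.99 ± 0.09 (6 and 5 arrays), and every NGMT array lay above every GMT array within each set. The related peptide gene Nppb rose by 0.73 ± 0.11, the granzyme gene Gzme by 0.91 ± 0.17† and the proteoglycan gene Epyc by 0.90 ± 0.21. Ryr2 fell (-0.84 ± 0.12), as did the phospholipid transporter Atp8a1 (-0.88 ± 0.09) and the sarcomeric M-band gene Myom2 (-0.79 ± 0.12). In the sarcomere list 0 of 27 rose and 4 fell (1 and 8 adjusted over the list alone), with Smpx at -0.55 ± 0.14 and Actn2 at -0.41 ± 0.10 (camera adjusted p = 4.19e-05, adjusted p = 0.346 with an estimated correlation). Of the atrial and natriuretic genes 2 of 8 rose and 0 fell (3 and 2 adjusted over the list alone) (camera adjusted p = 0.0359, adjusted p = 0.337 with an estimated correlation). Fibroblast and matrix genes gave 1 rises and 1 falls among 40 members (1 and 1 adjusted over the list alone), with a median of 0.09 (camera adjusted p = 1.87e-07, adjusted p = 0.431 with an estimated correlation). The call covered 199 genes (84 higher, 115 lower), and Nppa was the only gene called with a change of at least 2-fold (1). The count rested on set 1: the arrays of set 1 alone gave 674 genes and those of set 2 alone 1, Nppa. Nppa rose by 3.15 ± 0.09 in set 1 and by 2.87 ± 0.15 in set 2. The other genes named here were not called in set 2. In sets 1 and 2 Nppb was 1.16 ± 0.15 and 0.38 ± 0.10, Epyc 1.89 ± 0.06 and 0.10 ± 0.16, Ryr2 -1.39 ± 0.08 and -0.40 ± 0.10, Myom2 -1.26 ± 0.13 and -0.42 ± 0.12, Smpx -0.90 ± 0.20 and -0.27 ± 0.16 and Actn2 -0.84 ± 0.09 and -0.07 ± 0.09. Atp8a1 was -1.10 ± 0.11 and -0.70 ± 0.13, and Gzme, called in neither set alone, 0.74 ± 0.19† and 1.04 ± 0.21†. Leaving out 1 array at a time gave between 52 genes (without GMT replicate 2) and 379 (without GMT replicate 4).

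Adding Hand2 to GMT is the comparison of HGMT with GMT. Casq2, the cardiac calsequestrin of the sarcoplasmic reticulum, rose by 2.74 ± 0.08† and the cardiac transcription factor gene Tbx20 by 2.05 ± 0.13† (3 and 5 arrays). Over the same arrays the atrial genes Myl7 (-2.28 ± 0.21), Myl4 (-1.88 ± 0.09) and Nppa (-1.45 ± 0.12†) fell, as did cardiac troponin I, Tnni3 (-2.07 ± 0.12), and the muscle protein gene Smpx (-2.34 ± 0.17†). Of the atrial and natriuretic list 1 of 8 rose and 4 fell (1 and 4 adjusted over the list alone) (camera adjusted p = 0.0119, adjusted p = 0.107 with an estimated correlation). In the sarcomere list 5 of 27 rose and 7 fell (5 and 9 adjusted over the list alone) (camera adjusted p = 0.0601). Rises outside the lists were in Inmt, a methyltransferase gene (5.37 ± 0.13†), Pcolce2 (3.31 ± 0.09), the aldehyde dehydrogenase Aldh3a1 (3.26 ± 0.11) and glypican 3, Gpc3 (3.13 ± 0.09). Falls outside them were in the steroid dehydrogenase Hsd3b6 (-3.63 ± 0.25†), cholecystokinin, Cck (-3.31 ± 0.17), and Gpr165 (-3.18 ± 0.12†).

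Interferon-response genes fell in HGMT against GMT: 0 of 31 members rose and 26 fell (0 and 27 adjusted over the list alone), including Trim30a (-1.65 ± 0.11), Oas2 (-1.57 ± 0.17) and Rsad2 (-1.30 ± 0.21) (camera adjusted p = 2.03e-13, adjusted p = 0.206 with an estimated correlation). These genes also differed between sets 1 and 2 within GMT and NGMT. Adipocyte genes rose: 13 of 13 members rose and 0 fell (13 and 0 adjusted over the list alone), with Car3 at 2.00 ± 0.23 and Retn at 1.40 ± 0.29† (camera adjusted p = 2.99e-11, adjusted p = 0.0376 with an estimated correlation). Cell cycle genes gave 10 rises and 0 falls among 19 members (11 and 0 adjusted over the list alone), with cyclins Ccna2 (0.76 ± 0.09†) and Ccnb2 (0.75 ± 0.09) (camera adjusted p = 2.43e-04, adjusted p = 0.178 with an estimated correlation). Of the endothelial genes 6 of 13 rose and 1 fell (6 and 2 adjusted over the list alone), including VE-cadherin, Cdh5 (1.33 ± 0.07†), and the VEGF receptor Flt1 (1.24 ± 0.11) (camera adjusted p = 0.00131, adjusted p = 0.137 with an estimated correlation). Epithelial and mesothelial genes gave 5 rises and 1 falls among 9 members (5 and 1 adjusted over the list alone), with Wt1 at 1.46 ± 0.09† and Msln at 1.44 ± 0.11 (camera adjusted p = 0.00103, adjusted p = 0.204 with an estimated correlation). Altogether 3258 genes were called (1487 higher, 1771 lower; 211 at least 2-fold). The fit with 2 series named in the sample names, as planned before the data were examined, called 1403, and array weights 5023. The balance of directions moved, with 614 higher and 386 lower without a term, and 994 and 1086 on the arrays of set 2 alone. As direct differences after quantile normalization Oas2 (-0.92 ± 0.43) and Msln (0.24 ± 0.76) were not called, and Car3 was 3.71 ± 1.06.

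With NKX2.5 in both groups, HNGMT against NGMT is the comparison that adds Hand2 where NKX2.5 is present. Inmt (5.04 ± 0.13†), Gpc3 (3.26 ± 0.09), Aldh3a1 (3.26 ± 0.11), Casq2 (2.75 ± 0.08†) and Tbx20 (1.96 ± 0.13†) rose (3 and 6 arrays). Nppa (-2.23 ± 0.12), Myl7 (-2.16 ± 0.21), Myl4 (-1.88 ± 0.09) and Hsd3b6 (-3.22 ± 0.25†) fell. Atrial and natriuretic genes gave 1 rises and 6 falls among 8 members (1 and 6 adjusted over the list alone) (camera adjusted p = 0.00113, adjusted p = 0.0448 with an estimated correlation). Of the interferon-response genes 1 of 31 rose and 23 fell (1 and 24 adjusted over the list alone) (camera adjusted p = 2.08e-08, adjusted p = 0.340 with an estimated correlation). TGF-beta response genes gave 1 rises and 11 falls among 17 members (1 and 14 adjusted over the list alone), with Inhba at -1.01 ± 0.10 (camera adjusted p = 0.00324, adjusted p = 0.432 with an estimated correlation). Macrophage genes rose: 10 of 17 members rose and 0 fell (10 and 0 adjusted over the list alone), with Lyz2 at 2.76 ± 0.52 (camera adjusted p = 3.02e-05, adjusted p = 0.340 with an estimated correlation). Arrays overlapped, since Lyz2 was 7.66 in HNGMT replicate 3 and 8.59 in NGMT replicate 4, and on the arrays of HNGMT and NGMT alone Lyz2 was not called (adjusted p = 0.0803). The call covered 3865 genes (1066 higher, 2799 lower), against 1284 with the planned 2-level series term and 2145 on the arrays of set 2 alone. The excess of falls ended without a term (492 higher, 451 lower) but not on the arrays of set 2 alone (589 and 1556). HNGMT against GMT, which adds both factors, gave 4295 genes (1349 higher, 2946 lower; 3 and 5 arrays), with Inmt at 5.25 ± 0.13†, Casq2 at 2.77 ± 0.08†, Nppa at 0.76 ± 0.12 and Myl7 at -2.66 ± 0.21. With the planned 2-level series term this count was 1564. Without a term it split into 487 higher and 450 lower, and on the arrays of set 2 alone into 798 and 1672. The direct difference of Nppa was 0.11 ± 0.46 and not called, and against NGMT those of Aldh3a1 and Casq2 were 2.05 ± 0.57 and 1.80 ± 0.45†.

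Adding NKX2.5 to HGMT is the comparison of HNGMT with HGMT, in which Nppa rose by 2.22 ± 0.13† (3 and 3 arrays). Other rises were in macrophage genes, Lyz2 (3.25 ± 0.56†), Lyz1 (2.07 ± 0.40†) and Tyrobp (1.32 ± 0.26†), with Wfdc17 (2.68 ± 0.50†) and the myeloid receptor gene Lilrb4a (2.04 ± 0.38†). Of the macrophage list 4 of 17 rose and 0 fell (11 and 0 adjusted over the list alone) (camera adjusted p = 3.77e-13, adjusted p = 0.262 with an estimated correlation). Lyz2 signal was 11.03, 10.50 and 7.66 in HNGMT replicates 1, 2 and 3, against 6.29 to 6.61 in HGMT. Adipocyte genes gave 0 rises and 4 falls among 13 members (0 and 8 adjusted over the list alone), with perilipin 1, Plin1, at -0.58 ± 0.12 and Scd1 at -0.48 ± 0.08 (camera adjusted p = 2.90e-05, adjusted p = 0.262 with an estimated correlation). The call covered 76 genes (16 higher, 60 lower). As direct differences none was called in limma (0, with 1218 at an unadjusted p under 0.05), Nppa included (2.20 ± 0.52†). Both groups lie in set 2, so without a set term the estimate for Nppa hardly changed. Its standard error grew because the differences between sets in other groups stayed in the error of that fit. The count fell to 1 (Nppa) on the arrays of set 2 alone, to 1, 5 and 11 without HGMT replicates 1, 2 and 3 and to 14 without HNGMT replicate 1, and rose to 2407 and 3143 without HNGMT replicates 2 and 3. After quantile normalization 40 genes were called, 16 higher and 24 lower.

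The effect of NKX2.5 with Hand2 was tested against that without it as an interaction. Its limma test called 0 genes at the adjusted threshold and 2044 at an unadjusted p under 0.05. Array weights called 209 and leaving out HNGMT replicate 3 called 611. For Nppa the interaction is not read, because HGMT lay below the array median (6.16 ± 0.20, SD, n = 3) and its rise with NKX2.5 beside Hand2 is not exact.

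DMT against GMT replaces GATA4 with MYOCD. Smooth muscle genes rose: 19 of 22 members rose and 1 fell (19 and 1 adjusted over the list alone), including calponin, Cnn1 (4.78 ± 0.11†), smooth muscle myosin, Myh11 (4.50 ± 0.08†), the potassium channel subunit Kcnmb1 (4.09 ± 0.08†) and enteric actin, Actg2 (3.91 ± 0.12†) (3 and 5 arrays; camera adjusted p = 1.75e-34, adjusted p = 8.76e-05 with an estimated correlation). Skeletal muscle genes rose as well: 11 of 19 members rose and 2 fell (11 and 2 adjusted over the list alone), including skeletal alpha-actin, Acta1 (3.44 ± 0.06), the fast myosin Myh1 (2.07 ± 0.16†) and Mylpf (2.07 ± 0.05†) (camera adjusted p = 2.26e-10, adjusted p = 1.77e-04 with an estimated correlation). Sarcomere genes went both ways: 13 of 27 members rose and 9 fell (16 and 11 adjusted over the list alone), with Myom1 (3.01 ± 0.13†), the alpha-myosin heavy chain Myh6 (2.47 ± 0.11†) and Actc1 (2.21 ± 0.19) higher and Tnni3 lower (-2.26 ± 0.12) (camera adjusted p = 0.0146, adjusted p = 0.503 with an estimated correlation). Ion channel genes gave 7 rises and 1 falls among 12 members (7 and 1 adjusted over the list alone), with Popdc2 at 2.00 ± 0.11 and the pacemaker channel Hcn4 at 1.42 ± 0.10 (camera adjusted p = 7.18e-04, adjusted p = 0.0479 with an estimated correlation). Of the calcium-handling genes 7 of 19 rose and 4 fell (8 and 5 adjusted over the list alone), with Srl (2.79 ± 0.08) and Casq2 (2.33 ± 0.08†) higher and Ryr2 lower (-1.25 ± 0.15†) (camera adjusted p = 0.0417, adjusted p = 0.342 with an estimated correlation). Nppa rose by 3.76 ± 0.12.

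Interferon-response genes fell in DMT against GMT: 0 of 31 members rose and 28 fell (0 and 30 adjusted over the list alone), with Oas2 at -2.27 ± 0.17 and Trim30a at -1.91 ± 0.11 (camera adjusted p = 4.27e-25, adjusted p = 0.0479 with an estimated correlation). Complement C4b (-3.08 ± 0.26) and the interferon-inducible GTPase Iigp1 (-2.79 ± 0.14) fell as well. Adipocyte genes gave 0 rises and 8 falls among 13 members (0 and 8 adjusted over the list alone), with Car3 at -3.20 ± 0.23 and the adipogenic regulator Pparg at -1.21 ± 0.07 (camera adjusted p = 3.51e-07, adjusted p = 0.0479 with an estimated correlation). Cartilage and bone genes gave 5 rises and 0 falls among 11 members (6 and 0 adjusted over the list alone), with aggrecan, Acan, at 1.60 ± 0.13† and bone sialoprotein, Ibsp, at 1.50 ± 0.29 (camera adjusted p = 7.37e-04, adjusted p = 0.0479 with an estimated correlation). The mesothelial Msln (-1.34 ± 0.11) and urothelial Upk1b (-3.18 ± 0.12†) were lower. The call covered 2270 genes, 1201 higher and 1069 lower, of which 235 changed by at least 2-fold. Without a set term 1955 were higher and 280 lower, and with the planned 2-level series term 1649 and 535, with the median of all genes at 0.21 and 0.15. As direct differences after quantile normalization, Car3 (-1.37 ± 0.98), C4b (-2.03 ± 0.79) and Ibsp (0.74 ± 0.37) were not called, and Msln was -2.48 ± 0.70.

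**Figure D2:**
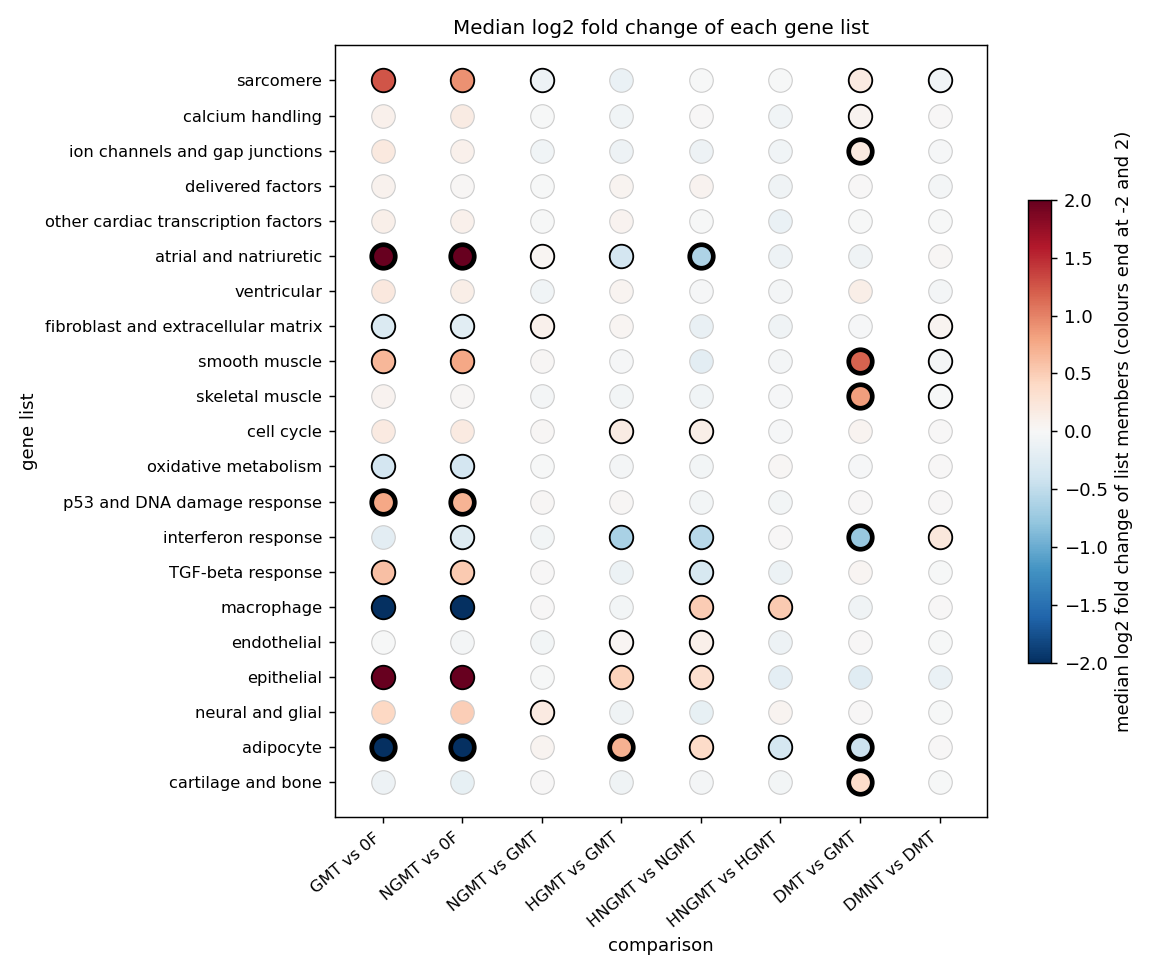
Median log2 fold change of the tested members of each gene list (vertical axis) in 8 comparisons (horizontal axis), as the colour of each dot. A thin black ring marks a camera call, a thick one a call that also held with an estimated correlation, and a grey ring no call; the smooth muscle median was 1.18 in DMT against GMT and the adipocyte median -3.66 in GMT against 0F.

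DMNT against DMT adds NKX2.5 beside MYOCD, and rests on 4 DMNT arrays and DMT replicate 4, the only DMT array of set 3. Pairs of DMNT arrays had exactly equal values for 17.3% to 31.3% of genes, against at most 3.71% inside any other group and set. DMT replicate 4 correlated with the DMNT arrays at a median r of 0.997. The source of this likeness was not tested, so how far these arrays are independent is unknown. The fit takes DMT replicate 4 to vary like the other groups. The values below are thus distances from that 1 array and cannot be read as a change between DMT and DMNT cultures. In DMNT the signal of Bst1, a cell-surface ADP-ribosyl cyclase, lay above it by 0.88 ± 0.17, that of Uprt by 0.71 ± 0.11, that of the complement protease gene C1s2 by 0.67 ± 0.10† and that of the chromatin remodeler Smarca2 by 0.49 ± 0.09. No sarcomere, smooth muscle or interferon-response member was called over all genes. The interferon-response list had a median of 0.22 (camera adjusted p = 1.43e-11, adjusted p = 0.546 with an estimated correlation; 1 member higher adjusted over the list alone) and the smooth muscle list -0.04 (camera adjusted p = 0.00605, adjusted p = 0.561 with an estimated correlation). The call covered 9 genes (8 higher, 1 lower). Without the third set it could not be made, and fits that ignore the scale of set 3 gave 9692 genes (no term, median of all genes 0.41) or 11156 (the planned 2-level series term). Direct differences after quantile normalization gave 373 higher and 346 lower. Among these direct differences Bst1 (0.06 ± 0.54), Uprt (0.05 ± 0.18) and Smarca2 (0.08 ± 0.09) were not called, and with the replicate number as a block none of the 4 named genes was called (0 genes in limma, 192 at an unadjusted p under 0.05). Leaving out a DMNT array ended the call of Bst1 (replicate 2, 3 or 4) and Smarca2 (replicate 1, 2 or 3).

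Against the effect of NKX2.5 beside GMT, the interaction for its effect beside DMT called 1 gene, Nppa (-2.84 ± 0.20), with 1 array for DMT. Nppa averaged 13.15 ± 0.04 in DMNT (SD, n = 4) against 13.00 in DMT replicate 4 within set 3. It averaged 11.37 ± 0.14 in DMT in set 2 (SD, n = 3). As a direct difference after quantile normalization the interaction for Nppa was -2.15 ± 0.59 and not called.

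HGMT, HNGMT, DMT and DMNT were compared with 0F across sets, with the limit named above. Tnnt2 was higher than in 0F in HGMT (5.10 ± 0.10, direct 5.51), HNGMT (4.96 ± 0.10, direct 5.34), DMT (4.77 ± 0.10, direct 5.30) and DMNT (4.65 ± 0.15, direct 5.58). Nppa was higher in HNGMT (3.64 ± 0.16†, direct 1.95), DMT (6.64 ± 0.16†, direct 5.18) and DMNT (6.79 ± 0.23†, direct 6.21). In HGMT, a case added after its values were seen, the fit gave 1.43 ± 0.16† for Nppa but the direct difference was -0.25 ± 0.52† and not called. Both groups lay below the array median on all arrays, so neither value measures a change. The signal was 6.16 ± 0.20 in HGMT in set 2 and 6.25 ± 0.02 in 0F in set 1 (SD, n = 3 each). The direct difference changed the size of some values by over 1.5 times, as for Casq2 in HGMT (4.64 ± 0.11†, direct 2.71), and ended the call of Car3 in HGMT (-5.28 ± 0.31, direct -1.04) and in HNGMT (-5.79 ± 0.31, direct -1.57). Smooth muscle genes were higher in DMT, as Cnn1 (5.63 ± 0.14†, direct 4.87) and Myh11 (4.38 ± 0.10†, direct 4.37), and in DMNT, as Myh11 (4.27 ± 0.15†, direct 5.05) and Actg2 (4.23 ± 0.24†, direct 5.48). In the smooth muscle list 18 of 22 rose and 2 fell (18 and 2 adjusted over the list alone) in DMT (camera adjusted p = 2.32e-09, adjusted p = 0.0201 with an estimated correlation). The DMNT arrays gave 18 rises and 2 falls among 22 members (18 and 2 adjusted over the list alone) of that list (camera adjusted p = 7.19e-11, adjusted p = 0.0110 with an estimated correlation). Skeletal muscle genes gave 12 rises and 2 falls among 19 members (12 and 2 adjusted over the list alone) in DMT (camera adjusted p = 2.47e-04, adjusted p = 0.0184 with an estimated correlation). Called higher by the direct difference as well were 17 smooth muscle genes in DMT and 17 in DMNT, and 11 skeletal muscle genes in DMT.

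Sarcomere genes gave 25 rises and 0 falls among 27 members (25 and 0 adjusted over the list alone) in HGMT (camera adjusted p = 1.12e-09, adjusted p = 0.0492 with an estimated correlation). In HNGMT 24 of 27 rose and 0 fell (25 and 0 adjusted over the list alone) (camera adjusted p = 6.55e-11, adjusted p = 0.0335 with an estimated correlation). In DMT 24 of 27 rose and 1 fell (24 and 1 adjusted over the list alone) (camera adjusted p = 2.58e-10, adjusted p = 0.0337 with an estimated correlation), and in DMNT 20 of 27 rose and 1 fell (21 and 1 adjusted over the list alone) (camera adjusted p = 6.32e-11, adjusted p = 0.0277 with an estimated correlation). Called higher by the direct difference as well were 17 sarcomere genes in HGMT, 17 in HNGMT, 19 in DMT and 17 in DMNT. The p53 target Perp was higher in HGMT (3.79 ± 0.07, direct 4.05) and DMT (3.98 ± 0.07, direct 4.18). The p53 list gave 22 rises and 2 falls among 27 members (22 and 2 adjusted over the list alone) in HGMT (camera adjusted p = 6.06e-09, adjusted p = 0.0106 with an estimated correlation). For DMT 22 of 27 rose and 2 fell (22 and 2 adjusted over the list alone) (camera adjusted p = 3.00e-07, adjusted p = 0.0184 with an estimated correlation). By both ways 20 were called higher in HGMT and 22 in DMT. Adiponectin, Adipoq, was lower in HGMT (-4.75 ± 0.29, direct -3.02) and DMT (-6.80 ± 0.29†, direct -5.30), and Lyz2 in HGMT (-6.70 ± 0.69†, direct -5.42) and DMT (-7.11 ± 0.69†, direct -5.99). HGMT gave 6241 called genes (3654 higher, 2587 lower), of which 4174 were called in the same direction by the direct difference. HNGMT gave 6071 (3233 higher, 2838 lower; 3971 by both), DMT 6888 (4226 and 2662; 4990 by both) and DMNT 5060 (3229 and 1831; 3908 by both). With the planned 2-level series term the counts were 4025, 3877, 5970 and 10464, and without a term 5788, 5325, 8092 and 10836. The median of all genes without a term was 0.19 for HGMT, 0.16 for HNGMT, 0.36 for DMT and 0.80 for DMNT, and the calls without it split into 4345 higher and 1443 lower, 3823 and 1502, 6794 and 1298, and 10126 and 710.

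All 6 combinations shared 2303 genes called higher and 1495 called lower than 0F, and 1244 and 1079 of these were also called by the direct difference. Sarcomere genes called higher in all 6 by both numbered 13 of 27 and included Tnnt2, Actc1, Myl7, Myl4, Ttn and Tpm1. The p53 list held 18 such genes higher and 2 lower of 27. Lower in all 6 by both were 12 of 13 adipocyte genes, 13 of 17 macrophage genes and 17 of 36 oxidative metabolism genes. Simulated unchanged groups against the same 0F arrays gave 0 shared genes in each direction in 20 runs. These groups were centred on the mean of the same 0F arrays, so the runs leave out the error of the shared controls. They therefore give no baseline for the shared counts. Independent lists of these sizes would share 11.6 higher and 1.15 lower, but the 6 comparisons are not independent. The 3 arrays of 0F cannot be split, so part of the excess may come from the shared controls. In the fit, HGMT, HNGMT, DMT and DMNT also share the set difference read from GMT and NGMT, and DMNT reaches 0F through DMT. The shared counts are thus not 6 separate findings of the same genes.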

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

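The counts of other splits of the samples were planned before the data were examined, apart from the choice to judge chance by splits within sets. Every other test in this part was chosen after the result it bears on was seen, so each explanation below remains a hypothesis.

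In 108 combinations of a group and a quantity, single arrays lay far from the rest of their group in 4, where chance gives about 1 in 20, or 5.4. The share of the group's range that lay between the array and its nearest neighbour was 0.857 for the fibroblast and extracellular matrix mean of DMNT replicate 4 (lowest), 0.774 for Myocd in NGMT replicate 3 (highest), 0.656 for Tbx5 in NGMT replicate 5 (highest) and 0.918 for Nkx2-5 in GMT replicate 5 (lowest). The gaps were small, at 0.06, 0.20, 0.13 and 0.16 log2 respectively. No biological explanation was tested for them. These quantities do not judge whole arrays. HNGMT replicate 1 had the lowest array weight, 0.0467, with GMT replicate 5 next at 0.273. Over genes, HNGMT replicate 1 differed from replicates 2 and 3 with an SD of 0.322 and 0.360, against 0.141 between replicates 2 and 3.

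Nppa stood out in the contrast of backgrounds: its change with NKX2.5 beside DMT minus that beside GMT was -2.84 on the log2 scale, but DMT enters with 1 array and the direct difference (-2.15 ± 0.59) was not called. A ceiling of the measurement stays open, since Nppa on the DMNT arrays lay 1.29 log2 below the brightest probe set, neither at the top nor clear of it by the whole difference between NGMT and GMT. An unusual level of Nppa in DMT replicate 4, through which alone DMNT is compared with DMT, stays open as well: Nppa there lay 1.63 above the other DMT arrays, at the 99.9th percentile of 1962 genes of a like level, whose median was 0.40. Its excess over them, 1.23, is smaller than the contrast, and Casq2 (1.39), Myh11 (1.51) and Myl7 (1.45) were raised in that array too, so a difference between sets cannot be told apart from it. An effect of MYOCD that replaces that of NKX2.5 on Nppa stays open too, and was not tested.

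The macrophage list, of 17 tested genes that stand in no other list, was called higher in HNGMT than in HGMT, but not with an estimated correlation (adjusted p = 0.262), and 4 of its genes were called. After quantile normalization the list's adjusted p in camera was 4.53e-12. Both groups lie in set 2, whose arrays already had nearly equal distributions, so this value does not decide on scaling. Macrophages or their RNA in some HNGMT cultures may be the source: over list members, the excess in HNGMT followed the excess of 0F over GMT (Spearman rho 0.743), and Lyz2 stood at 11.03, 10.50 and 7.66 log2 in HNGMT replicates 1 to 3, with Tyrobp at 8.38, 7.33 and 6.38. A response of every HNGMT culture to NKX2.5 beside Hand2 cannot be excluded, because the lowest HNGMT array lay 0.12 log2 above the highest HGMT array in the list mean. The labels name zeocin selection, which would remove cells without an active Troponin T reporter if complete.

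HGMT and DMT differed from GMT in 3258 and 2270 genes, and NGMT in 199. Quantile normalization gave 3291 genes for HGMT and 2283 for DMT. It could change little, since the arrays of set 2 already had nearly equal distributions (largest mean distance 0.0466 log2). It therefore does not decide on scaling. The difference that parts set 1 from set 2, whose source the labels do not give, was not seen in HGMT over all genes. Its correlation with the difference from GMT was -0.0271 (48.3% of called genes with the same sign). Parts of opposite sign can cancel there, since interferon-response and epithelial genes moved toward set 1 and adipocyte genes away from it. It stays open for such parts, and for DMT, where the correlation was 0.185 (64.4%). The differences recurred in other arrays with the same factor (r = 0.862 for Hand2 in HNGMT against NGMT, r = 0.790 for MYOCD in DMNT), which an effect of the factor needs. For Hand2 both differences lie within set 2. For MYOCD, DMNT arrays of set 3 were set against NGMT arrays of set 2 after quantile normalization, without a set term. A difference between sets is part of that value. Cultures grown on different occasions cannot be told apart from an effect of either factor, because the labels give no culture date.

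Other splits of the same arrays into groups of the same sizes were fitted with the set term kept. Most of them move arrays between sets, unlike the real comparison, so only those that keep the arrays of each group in each set were used to judge chance. For NGMT against GMT 2 of 100 such splits, the real one included, called at least its 199 genes (highest other 279). Without that condition it was 3 of 100 (highest other 326). The share is under 0.05, but chance is not excluded for these genes as a whole. Set 1 alone called 674 genes and set 2 alone 1, Nppa. Elsewhere the splits within sets are too few for a share under 0.05: GMT against 0F (1 of 56 of all splits, the real one included, called as many, 7333, highest other 5292; 0 among 10 within sets), NGMT against 0F (1 of 84, 7422, highest other 5635; 5635 among 20 within sets), HGMT against GMT (1 of 56, 3258, highest other 1392; 1392 among 20 within sets) and HNGMT against GMT (1 of 56, 4295, highest other 2161; 1619 among 20 within sets). The same holds for HNGMT against NGMT (1 of 84, 3865, highest other 1581; 1581 among 20 within sets) and DMT against GMT (1 of 100, 2270, highest other 1821; 1203 among 20 within sets). Where 20 splits lie within sets, they include the exchange of the 2 whole groups in the set with 3 arrays of each. That exchange turns the real difference round in that set. The highest counts there may come from it, so they give no measure of chance.

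For the remaining comparisons the splits decide nothing. No set holds both groups for HGMT (1 of 10, 6241, highest other 0), HNGMT (1 of 10, 6071, highest other 833), DMT (2 of 35, 6888, highest other 6888) and DMNT (1 of 35, 5060, highest other 0) against 0F. Their other splits put arrays of 1 set against each other, which the real one does not, except 1 for DMT that differs from it in DMT replicate 4 alone. DMNT against DMT (1 of 35, 9, highest other 1) and the interaction beside DMT (7 of 100, 1, highest other 991) rest on DMT replicate 4 alone in the real split. For HNGMT against HGMT splits are too few (2 of 10, 76, highest other 359). The interaction with Hand2 called 0 genes, so all 100 of 100 splits called as many (highest other 1261). The 359 genes of another split of the HNGMT and HGMT arrays point to a structure of these samples whose source was not tested: the SD over genes of the difference of HNGMT replicate 1 from replicates 2 and 3 was 0.322 and 0.360. The splits of the interactions exchange arrays between combinations that differ in many genes (3258 for HGMT and 2270 for DMT against GMT), so their 1261 and 991 genes show that structure at least.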

How the results depend on the processing

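Most alternatives were chosen before the data were examined. Chosen after the data were seen were the direct difference, the fit without set 3, the fits on 1 set and the lists without HNGMT replicate 1. The 2-level series term and the constant of 16 belonged to the plan for the fit itself and became alternatives when that fit was changed after the data were seen. The counts for GMT, NGMT and DMT against 0F and for DMT against GMT stayed within 1.5 times under every alternative run. Where no reason is given, the cause was not tested.

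With the 2-level series term the counts were 4025 for HGMT, 3877 for HNGMT and 10464 for DMNT against 0F, 33 for NGMT, 1403 for HGMT and 1564 for HNGMT against GMT, 1284 for HNGMT against NGMT, 6 for HNGMT against HGMT, 11156 for DMNT against DMT and 9980 for the interaction beside DMT. That term leaves the scale of set 3 in the DMNT values. Without a term they were 10836 for DMNT against 0F, 2, 1000 and 937 for NGMT, HGMT and HNGMT against GMT, 943 for HNGMT against NGMT, 0 for HNGMT against HGMT (366 at an unadjusted p under 0.05), 9692 for DMNT against DMT and 7969 for the interaction beside DMT, and 520 genes were lower in all 6 combinations. The list tests without it turned the sign of the interferon response (1.21e-06) and smooth muscle lists (0.641) in DMNT against DMT and of calcium handling in DMT against GMT (0.954; adjusted p). Nppa in HGMT against 0F turned to -0.0877 without a term and to -0.25 as a direct difference. Direct differences gave 7787 for DMNT against 0F, 4, 2024 and 2506 for NGMT, HGMT and HNGMT against GMT, 0 for HNGMT against HGMT (1218 unadjusted), 719 for DMNT against DMT and 0 for the interaction beside DMT (1946 unadjusted). Fits without a set term leave the differences between sets in the error, which widens it for groups of 1 set, as HNGMT and HGMT.

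Fewer arrays gave lower counts for most comparisons. Series 2 alone gave 3 for NGMT against GMT, 14 for HNGMT against HGMT and 5 for DMNT against DMT. Set 2 alone gave 1, 2080 and 2470 for NGMT, HGMT and HNGMT against GMT, 2145 for HNGMT against NGMT and 1 for HNGMT against HGMT, and set 1 alone 674 for NGMT against GMT. Without set 3 the counts were 101 for NGMT against GMT and 6 for HNGMT against HGMT. The compared groups alone gave 19 and 965 for NGMT and HNGMT against GMT, 1359 for HNGMT against NGMT, 1 for HNGMT against HGMT, 16 for DMNT against DMT and 13 for the interaction beside DMT. Array weights gave 5023 for HGMT against GMT, 816 for HNGMT against HGMT, 158 for DMNT against DMT, 209 for the interaction with Hand2 and 59 for that beside DMT. Quantile normalization with the set term gave 40 for HNGMT against HGMT, 14 for DMNT against DMT and 2 for the interaction with Hand2. No filter gave 44 for HNGMT against HGMT and 2 for the interaction beside DMT. For the interactions with Hand2 and beside DMT, a constant of 64 gave 10 and 6, and one of 16 gave 1 and 3.

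Replicate numbers gave no clear pairing of the arrays. Of pairs with the same number in their titles 7 of 21 correlated above 0.1 (median 0.0214), against 24 of 90 pairs with different numbers. By the number in the sample name it was 9 of 30 against 22 of 81. Deviations inside groups of so few arrays depend on each other, so this check is weak and does not exclude pairing. With the title number as a replicate block the counts were 2088 and 2208 for HGMT and HNGMT against GMT, 1401 for HNGMT against NGMT, 19 for HNGMT against HGMT and 0 for DMNT against DMT (192 unadjusted, limma). With the name number as a block they were 4 for NGMT against GMT and 1 for HNGMT against HGMT. Other block counts stayed within 1.5 times.

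Leaving out 1 array at a time gave 6792 to 7401 genes for GMT against 0F, 6831 to 7362 for NGMT against 0F, 5865 to 5927 for HGMT against 0F, 5646 to 6637 for HNGMT against 0F, 6479 to 6889 for DMT against 0F, 4794 to 4894 for DMNT against 0F, 2557 to 3422 for HGMT against GMT, 3554 to 5151 for HNGMT against GMT, 3248 to 4715 for HNGMT against NGMT and 1743 to 2417 for DMT against GMT. For NGMT against GMT the range was 52 to 379, with 52 without GMT replicate 2, 66 without GMT replicate 1, 92 and 87 without NGMT replicates 1 and 2, and 379 without GMT replicate 4. For HNGMT against HGMT it was 1 to 3143, with 1, 5 and 11 without HGMT replicates 1, 2 and 3, and 14, 2407 and 3143 without HNGMT replicates 1, 2 and 3. For DMNT against DMT it was 5 to 13, with 5 without DMNT replicate 2 or 3. The interaction with Hand2 ran from 0 to 611 (1764 at an unadjusted p under 0.05 without GMT replicate 2), with 1 without GMT replicate 1, NGMT replicate 1 or NGMT replicate 5, 2 without HGMT replicate 2, 65 without GMT replicate 4, 349 without HNGMT replicate 2 and 611 without HNGMT replicate 3. That beside DMT ran from 1 to 4, with 2 without DMT replicate 1, NGMT replicate 4 or DMNT replicate 2, 3 without NGMT replicate 3 or 5, and 4 without GMT replicate 4. Where an arm kept 1 array, it was taken to vary like the other groups. The list tests without HNGMT replicate 1 called 111 pairs.

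Camera called 116 of the list and comparison pairs and 37 with an estimated correlation, and fry 168, of which 105 were called by camera in the same direction. Of the 1091 gene and comparison pairs of the naming rule, 59 changed direction in an alternative with a call in either fit, 24 of them in DMNT against DMT, and 0 when 1 array was left out. Of the 24814 values of these pairs under alternatives, 23147 kept direction and side of the threshold, 1293 lost the call in the same direction, 142 gained it, 109 turned direction with a call in either fit and 123 without one. A constant of 64 shrank by over 1.5 times values of dim genes: Nes in GMT against 0F, Ccna2, Cdh5, Nppa, Tbx20 and Wt1 in HGMT against GMT, Hsd3b6 and Tbx20 in HNGMT against NGMT, Lilrb4a and Tyrobp in HNGMT against HGMT, Acan, Kcnmb1 and Mylpf in DMT against GMT and Gzme in NGMT against GMT. Not run, since the arrays do not allow them: the block by sample names for DMNT against DMT and its interaction, the compared groups alone for HGMT, HNGMT, DMT and DMNT against 0F, and DMNT against DMT or its interaction without DMT replicate 4. Genes dim on all arrays were not tested, so no statement covers them.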
